A study of Mus musculus with 7 samples.

How the data were processed

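Total RNA of mouse fetal liver cells was measured on 7 single-colour short-oligonucleotide arrays. The deposited values are signal intensities on a linear scale, 1 per probe set, with a trimmed mean near 250 on each array. They were made with GCOS per the submitters' processing notes for the 3 arrays of the second deposit set; the software used for the first set is not given in the sources used here. Of the 7 arrays, 6 lie in 1 deposited table and the feeder array lies alone in another, under a different array platform. The 2 tables were matched by probe set name. Groups were taken from the sample titles, as were replicate numbers where given, and a title without a number was read as replicate 1. The titles name no deposit set. The split into a first and a second set was inferred here, and the second set holds the arrays whose titles name sample 2 or 3. The labels do not say which samples came from separate cultures or animals, so p-values measure the spread between these samples, which may be partly technical. No 2 of the arrays held identical values.

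Each array was scaled to a 2% trimmed mean of 500, values under 64 were set to 64 and log2 was taken; a difference against a value at this floor is a lower bound. Of the 22690 probe sets, 64 controls were left out, 20380 were paired with 1 gene, 691 with several and 1555 with none in the annotation, and only those with 1 gene were used, which gave 12393 genes. No symbol needed updating against the GRCm38.p6 gene table. For each gene the probe set with the highest mean log2 signal over the 6 arrays of the larger table was kept. Genes with a signal above 100 on at least 2 of the 5 sorted arrays were tested, which left 8591.

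Sca1+ was compared with Sca1- using limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 1 mean per group, 6 arrays) with Benjamini-Hochberg adjustment at 0.05. The main design has group as its only term. The deposit set as a block is an alternative fixed in advance, and its values are given beside the main ones because both sets hold both fractions. Residual degrees of freedom were 3 without and 2 with the block. Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, and with an estimated correlation and fry as alternatives; 28 lists were fixed and 25 could be tested. The comparisons of the feeder with the sorted fractions had been designed as tests, but the feeder array lies in a separately deposited table, so neither the gene test nor the list test was run and values are described. For comparisons of single arrays, a list's median was placed among 10000 random lists of the same size matched on mean level.

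The genes named were fixed by rule: for the tested contrast the 10 highest and 10 lowest differences among genes past the threshold, filled up with genes of the largest difference whose groups do not overlap; for described lists up to 4 members with the smallest p; and for comparisons without a test the 10 highest and 10 lowest differences with the higher signal above 500. Genes of the sort (Ly6a and Pecam1) were always to be named. No probe set was paired with Ly6a, and Pecam1 has 1 probe set. Probe sets without a gene or with several were skipped.

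The gene test was checked on data simulated from the means and spread of these 8591 genes with 200 genes changed. With group only, 0 of 50 genes changed 2-fold, 16 of 50 changed 4-fold, 42 of 50 changed 8-fold and 49 of 50 changed 16-fold were recovered. With the block, 8, 43, 50 and 50 of 50 were. Of 8391 unchanged genes, 12 were called with group only and 9 with the block. The simulated noise was normal and independent between arrays, and with group only it held no shift between deposit sets. Recovery in the measured arrays, which differ by deposit set, can therefore be lower than in the simulation. A shifted list was recovered and 0 of 20 unshifted lists were called in either fit. The simulated genes varied independently, so this does not show how often lists of correlated genes are called by error. In the data the estimated correlation was 0.63 for granulocyte, 0.15 for G2 and M phase and 0.29 for S phase genes.

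The lists, tests, named-gene rule and alternatives were chosen before the data were examined. The alternatives were quantile normalization, median scaling, floors of 16 and 128, a pseudocount of 32 in place of a floor, no filter or a signal minimum of 300, all probe sets or the mean of a gene's probe sets, no intensity trend, the deposit set or the replicate number as a block, only the compared groups, a 2-fold minimum, and leaving out each sorted array. Running these on the fit with the deposit set as a block was added after seeing the data. Figures were drawn with matplotlib 3.10.9.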

Results

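RNA of mouse fetal liver cells was measured on 7 short-oligonucleotide arrays, each with 22690 probe sets. The arrays cover liver endothelial progenitors sorted as positive (Sca1+, n = 2) or negative (Sca1-, n = 3) for Sca1, unsorted progenitors (n = 1) and a feeder cell layer grown from fetal liver (n = 1). Sca1, the product of Ly6a, is a surface antigen used to enrich stem and progenitor cells. The arrays were grouped into a first deposit set of 4 (1 array of each group) and a second of 3 (Sca1+ replicate 2 and Sca1- replicates 2 and 3). This split was inferred and is not named in the titles. The number of arrays limits the precision, and the unsorted and feeder values have no replicate. The feeder array was deposited under a different array platform from the others, so every comparison with it also crosses platforms. Values are signals scaled to a trimmed mean of 500 per array, and differences are on the log2 scale with a floor of 64.

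Leukocyte transcripts were abundant on all arrays, while the number of endothelial transcripts above the signal minimum of 100 varied between arrays. Of 29 pan-endothelial genes measured, 9 and 22 exceeded it on the Sca1+ arrays, 14, 12 and 12 on the Sca1- arrays, 23 on the unsorted array and 12 on the feeder array. Ptprc, which encodes the leukocyte antigen CD45, had signals of 10505 and 4777 on the Sca1+ arrays and 13668, 7586 and 6501 on the Sca1- arrays. Pecam1, which encodes the endothelial adhesion molecule CD31, had signals of 15.0 and 206 on the Sca1+ arrays, 23.2, 117 and 25.8 on the Sca1- arrays, 117 on the unsorted array and 124 on the feeder array. The difference of Pecam1 between Sca1+ and Sca1- was 0.55 ± 0.63 (SE) and did not pass the test. Of 24 macrophage and Kupffer cell genes measured, 19 exceeded 100 on all 5 sorted arrays, against 7 of the pan-endothelial genes. Probe sets for bacterial control transcripts, taken here as background controls, reached up to 170 on an array. Pecam1 lay below the highest background control on 4 of the 7 arrays. These controls read background only if no such transcripts were added to the samples, which the sources used here do not say. No probe set was paired with Ly6a in the annotation used, and the sorting antigen itself was therefore not read.

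The arrays also differed in the 3' to 5' ratio of control probe sets and in the level of mesenchymal transcripts. The ratio of the 3' to the 5' probe set of Actb, which rises when transcripts are truncated, was 6.83 on Sca1+ replicate 1 and 13.5 on Sca1- replicate 1, between 1.87 and 2.37 on the second-set arrays, 1.01 on the unsorted array and 1.03 on the feeder array. Col1a1, which encodes a fibrillar collagen chain, had signals of 79.4 and 32.6 on the first-set sorted arrays and 20565, 8319 and 8775 on the second-set arrays. The median log2 signal of the fibroblast and mesenchymal list was 6.41 and 6.54 on the first-set sorted arrays, 10.82, 8.69 and 8.95 on the second-set arrays and 10.86 on the feeder array. Across 8591 genes, which are not independent replicates, Pearson's r was 0.97 between Sca1- replicates 2 and 3, 0.80 and 0.79 between each of them and Sca1- replicate 1, and 0.83 between the Sca1+ replicates. Between the fractions it was 0.92 for Sca1+ replicate 2 with each of Sca1- replicates 2 and 3, 0.88 and 0.87 for Sca1+ replicate 1 with the same arrays, 0.85 for the first-set pair and 0.69 for Sca1+ replicate 2 with Sca1- replicate 1. Sca1+ replicate 2 had r = 0.93 with the feeder array.

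**Figure D1:**
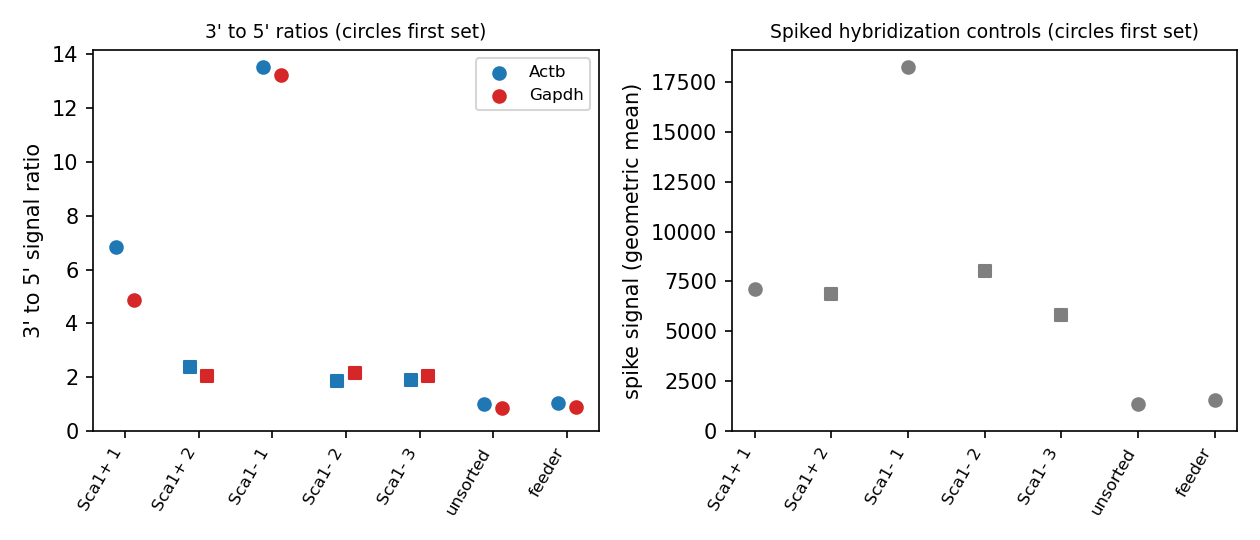
Ratio of 3' to 5' signal for Actb and Gapdh (left axis from 0, a ratio) and the geometric mean signal of spiked hybridization controls (right panel, scaled signal) on each of the 7 arrays, circles for the first deposit set and squares for the second. Sca1- replicate 1 has the highest Actb ratio, 13.5, and the highest spike signal, 18256.

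The comparison of Sca1+ with Sca1- progenitors asks which transcripts differ between the fractions. With no gene past the threshold, the 20 genes named here are those of largest difference whose arrays do not overlap between the fractions, so their separation comes from that rule. Among them neutrophil granule and granulocyte precursor transcripts had the largest differences. Ngp, a granule gene outside the rule and named after its values were seen, overlapped, with signals of 34150 and 1464 on the Sca1+ arrays against 95069, 36063 and 31233 on the Sca1- arrays. Pglyrp1, which encodes a bactericidal peptidoglycan recognition protein, was lower by a log2 difference of -5.43 ± 0.69 (SE), with signals of 402 and 75.4 on the Sca1+ arrays against 6249, 8415 and 8098 on the Sca1- arrays. The granule proteins Lcn2 (-4.03 ± 1.5), Camp (-4.03 ± 1.46) and Ltf (-3.69 ± 1.35), the myeloid enzyme Mpo (-3.95 ± 1.32), the chitinase-like genes Chil3 (-4.02 ± 1.53) and Chil1 (-3.70 ± 1.51), Stfa3 (-3.94 ± 1.15), Wfdc21 (-3.97 ± 1.14) and the transcription factor gene Nfe2 (-3.71 ± 1.09) lay in the same direction. On the side of higher Sca1+ signal the differences were smaller, and the named genes included H2-Aa (1.88 ± 0.72) and H2-Ab1 (1.75 ± 0.60), which encode class II antigen presentation chains, and Ms4a1 (1.83 ± 0.61), which encodes the B-cell antigen CD20. The other genes named by the rule were Fcrls (2.05 ± 0.65), Gpr31b (1.94 ± 0.54), Man1a (1.88 ± 0.69), Cd2ap (1.85 ± 0.60), the complement gene Cfb (1.81 ± 0.80), Spon1 (1.81 ± 0.49) and Atp4b (1.77 ± 0.43). The floor was reached on all 3 Sca1- arrays for Atp4b, on 2 for H2-Ab1 and on 1 for Cfb, so the size of these differences depends on the floor. Gpr31b, Spon1, Cfb and Atp4b also lay below the highest background control of 170 on Sca1- replicate 1, and Ms4a1, at 75.6, below that of 88.2 on Sca1- replicate 2.

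None of these genes passed with group as the only term. Of 8591 genes tested with limma, 0 had an adjusted p under 0.05, the smallest was 0.710, and 292 had an unadjusted p under 0.05 (95 higher and 197 lower in Sca1+) where 430 would be met by chance. With the deposit set as a block, 85 genes passed, 0 higher and 85 lower in Sca1+. In that fit Pglyrp1 (-5.57 ± 0.60, adjusted p = 0.0154), Nfe2 (-4.16 ± 0.31, adjusted p = 0.00545), Chil1 (-4.36 ± 0.22, adjusted p = 0.00437), Camp (-4.62 ± 0.57, adjusted p = 0.0294), Lcn2, Chil3, Wfdc21, Stfa3, Ltf and Asprv1 passed, while Mpo (adjusted p = 0.141) did not. Within the first set, with 1 array of each fraction, the difference of Pglyrp1 was -3.96, of Camp -3.09 and of Nfe2 -3.53. Within the second set, with 1 Sca1+ and 2 Sca1- arrays, it was -6.78, -5.77 and -4.64. Pglyrp1, Nfe2 and Asprv1, with signals of 75.4, 76.6 and 24.2 on Sca1+ replicate 2, lay below that array's highest background control of 82.0. The size of their differences is therefore uncertain, and Asprv1 was at the floor there. None of the genes with higher Sca1+ signal passed in the blocked fit either, where the rule added Lgmn (2.03 ± 0.62), Rhoq (1.91 ± 0.64), Cav2 (1.86 ± 0.60), Gja1 (1.84 ± 0.43) and Cd72 (1.83 ± 0.31, adjusted p = 0.0720). Cav2 and Gja1 also lay below the highest background control on Sca1- replicate 1. Both Sca1+ arrays lay above every Sca1- array for 1043 genes (12.1%) and below every one for 726 (8.45%), where chance gives 10% in each direction. A higher floor or the absence of a filter took the blocked count to 0. Without the block and without the filter 1 gene, Smad9, passed (named after its value was seen).

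Of 25 gene lists tested with camera at a preset correlation, 3 passed, all lower in Sca1+. Granulocyte and mast cell genes had a median difference of -3.07 over 13 tested members (adjusted p = 1.68e-09, but 0.643 with an estimated correlation), of which 9 were lower with an unadjusted p under 0.05 and 0 higher; Elane (-3.39 ± 0.86) and S100a9 (-3.07 ± 0.81) had the smallest p. Adjusted over the list alone, 2 members passed, and with the deposit set as a block 4 passed over all genes tested and 10 adjusted over the list alone. The mast cell and eosinophil genes Cpa3, Tpsab1 and Prg2, named after their values were seen, had an unadjusted p between 0.686 and 0.850. The median was -1.42 within the first set and -4.51 within the second. Genes of G2 and M phase, which run mitosis, had a median of -1.10 (adjusted p = 4.91e-21, but 0.394 with an estimated correlation), and all 28 tested members had a difference below 0, with 21 lower on both Sca1+ arrays than on every Sca1- array. Bub1b (-2.14 ± 0.48), Cks2 (-1.47 ± 0.36), Aurka (-1.36 ± 0.38) and Ube2c (-1.47 ± 0.50) had the smallest p, 0 members passed adjusted over the list alone, 21 did so with the block, and the median was -0.81 in the first set and -1.30 in the second. DNA replication and S phase genes had a median of -0.23 over 23 members (adjusted p = 0.0155, but 0.928 with an estimated correlation), 3 of them lower with an unadjusted p under 0.05, among them Rrm2 (-1.39 ± 0.45), Cdc45 (-1.52 ± 0.57) and Uhrf1 (-1.27 ± 0.51). Their median was 0.32 in the first set and -0.63 in the second, and the call was lost without Sca1- replicate 2 or 3, without Sca1+ replicate 2 and with the replicate number as a block. With fry, which does not compare a list with other genes, the adjusted p was 0.569 for granulocyte, 0.222 for G2 and M phase and 0.974 for S phase genes.

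Lists of other cell types did not pass with group as the only term. Macrophage and Kupffer genes had a median of 0.37 (adjusted p = 0.0654), with 17 of 22 tested members above 0, led by Adgre1 (1.75 ± 0.58) and Fcgr1 (1.30 ± 0.44), and 0 members passed. This list passed, higher in Sca1+, with quantile normalization, signal above 300, all probe sets, the mean of a gene's probe sets, the replicate number as a block and without Sca1+ replicate 2, while its adjusted p was 0.600 with an estimated correlation. Haematopoietic stem and progenitor genes had a median of -0.31 (adjusted p = 0.0654), with Itga2b (-1.11 ± 0.39), Myb (-1.87 ± 0.68), Gfi1 (-1.38 ± 0.54) and Lyl1 (-0.93 ± 0.39) lowest in p. They passed, lower in Sca1+, with the higher floor, all probe sets, only the compared groups and without Sca1+ replicate 1, while their adjusted p was 0.600 with an estimated correlation. Pan-endothelial genes had a median of 0.39 (adjusted p = 0.803, 0.977 with an estimated correlation) over 18 tested members. Their median was -0.51 within the first set and 0.81 within the second. It was 0.86 without Sca1+ replicate 1 and -0.25 without Sca1+ replicate 2. Megakaryocyte and platelet genes had a median of -0.21 (adjusted p = 0.262, 0.798 with an estimated correlation) and passed with the higher floor, the mean of a gene's probe sets and only the compared groups. Interferon-stimulated and class I antigen presentation genes had a median of 0.22 (adjusted p = 0.248), and passed, higher in Sca1+, with all probe sets, without Sca1+ replicate 2 and without Sca1- replicate 1, while their adjusted p was 0.928 with an estimated correlation. Fibroblast and mesenchymal genes had a median of 0.25 (adjusted p = 0.887), -0.30 within the first set and 1.59 within the second. Their direction depended on the Sca1+ array kept, with medians of 2.57 without Sca1+ replicate 1 and -2.02 without Sca1+ replicate 2. With the deposit set as a block they passed at an adjusted p of 0.00329 (adjusted p = 0.836 with an estimated correlation). In that blocked fit 7 lists passed: granulocyte, G2 and M phase and S phase genes lower, and fibroblast, basement membrane, secreted factor and immediate early genes higher. With an estimated correlation none of the lists passed in the blocked fit, where the smallest adjusted p was 0.747.

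**Figure D2:**
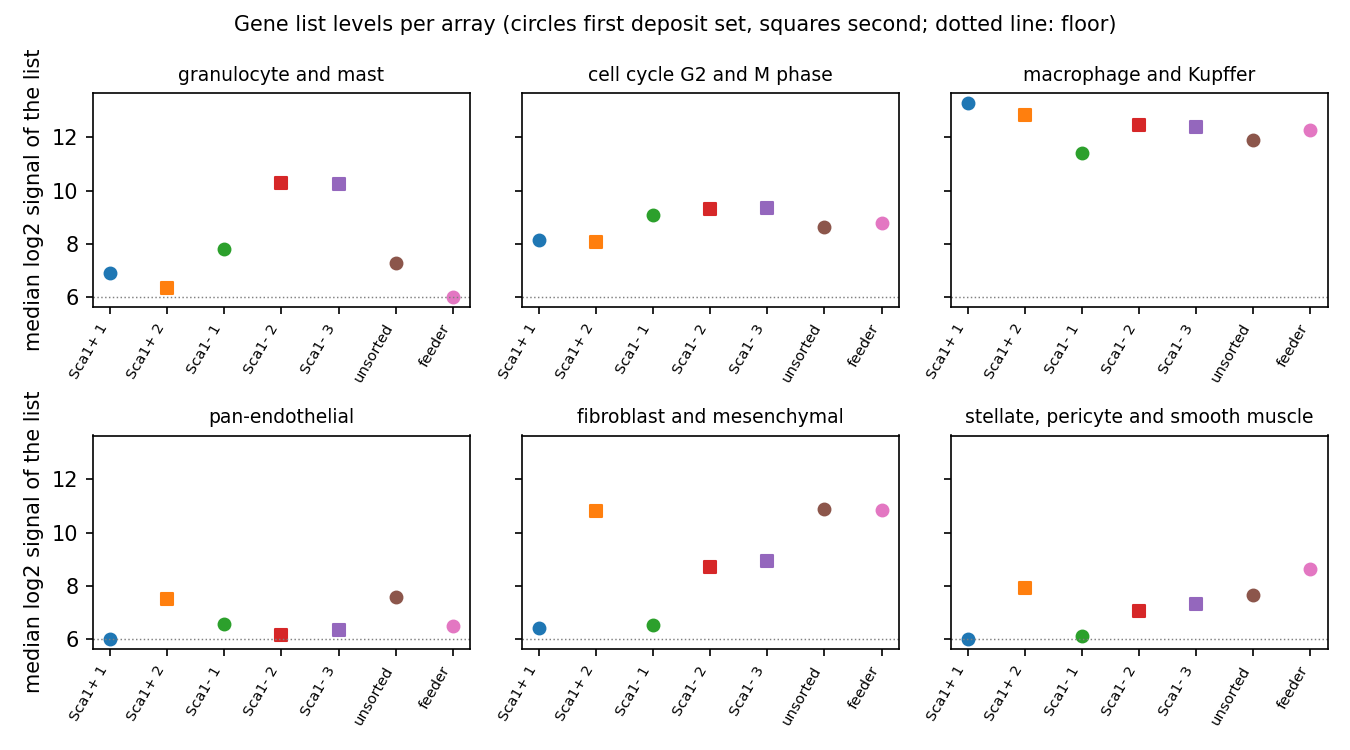
Median log2 signal of 6 gene lists on each of the 7 arrays, circles the first deposit set and squares the second; the dotted line is the floor. The fibroblast and mesenchymal list lies at 6.41 and 6.54 on the first-set sorted arrays and at 8.69 or above on the others, and the G2 and M phase list is lower on both Sca1+ arrays than on the 3 Sca1- arrays.

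The feeder layer and the unsorted progenitors were set side by side as 1 array each. They came from tables deposited separately under different platforms, so no test was made. Stellate cell, pericyte and smooth muscle transcripts stood higher on the feeder array. Des, which encodes the muscle intermediate filament desmin, had a signal of 1700 against 79.2, a log2 difference of 4.42. The rule also named in this direction Itsn1 (3.89), Fxr2 (3.19) and Lima1 (3.12), which were at the floor on the unsorted array, the cytokine gene Tnf (3.07), Ankrd1 (3.03), the neutrophil chemokine gene Cxcl1 (3.03), Tm4sf1 (2.86), Prss23 (2.69) and the smooth muscle gene Cnn1 (2.68). Des, Itsn1, Fxr2, Lima1, Tnf, Ankrd1, Tm4sf1 and Prss23 lay below the unsorted array's highest background control of 170, so the size and order of their differences are uncertain. Of 18 stellate cell, pericyte and smooth muscle genes, 9 were at least 2-fold higher on the feeder array, and their median of 1.05 lay at percentile 100 of 10000 random lists matched on level. Matrix protease and inhibitor genes (median 0.54), secreted growth factors and cytokines (median 0.35) and chemokine and inflammatory genes (median 0.57, percentile 99.99) also lay at or near the top of their random lists. So did immediate early and heat shock genes (median 0.45, percentile 100), S phase genes (0.49, percentile 100), hypoxia and glycolysis genes (0.44, percentile 99.98), G2 and M phase genes (0.29, percentile 99.86) and basement membrane genes (0.31, percentile 99.21).

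Granulocyte genes stood lowest on the feeder array: the list's median was -3.64, at percentile 0, and 10 of 11 members were at least 2-fold lower. Asprv1 (-4.51 or lower, at the floor on the feeder array), Stfa3 (-4.39), Ltf (-4.22), Pglyrp1 (-4.09), S100a8 (-3.90), Camp (-3.87), Dmbt1 (-3.84), Lcn2 (-3.83), S100a9 (-3.66) and Ngp (-3.64) had the largest differences. Hepatoblast and hepatocyte genes had a median of -1.16 (percentile 0.01), with 12 of 20 at least 2-fold lower. Fibroblast genes went both ways, with a median of 0.05 at percentile 34.5. Of 27 members, 3 were at least 2-fold higher and 2 at least 2-fold lower on the feeder array. Over 9751 genes, 398 were at least 2-fold higher and 1548 at least 2-fold lower on the feeder array, with a median of -0.13. That split depended on the scaling, with 667 and 759 after quantile normalization and 880 and 688 after median scaling, which moved the median of all genes to 0.28; the granulocyte median was then -4.49 and -3.29, and the stellate median 1.24 and 1.41.

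The unsorted progenitors were compared with the sorted fractions gene by gene, with no test because there was 1 unsorted array. Highest on the unsorted array relative to the mean of the 2 fractions were Dmbt1 (3.93) and the hepatoblast marker Dlk1 (3.44), followed by Islr (3.30), Postn (3.28), Dcn (3.19), Cdh11 (3.18), Col1a1 (3.17), Sox4 (3.17), Pdgfra (2.98) and Ptn (2.96). Col1a1 had a signal of 13192 on the unsorted array but 20565 on Sca1+ replicate 2. Of these 10 genes all but Dcn were at the floor on at least 1 sorted array, so the size of their differences depends on the floor. The fibroblast list's median was 2.23 above the sorted mean, but only 3 of 27 members were at least 2-fold above all 5 sorted arrays. Dmbt1, which is in no list, had a signal of 976 on the unsorted array and at most 64.8 on a sorted array. Hepatoblast and hepatocyte genes had a median of 1.29, with 8 of 20 at least 2-fold above all 5 sorted arrays, and biliary and epithelial genes a median of 1.86, with 5 of 8.

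Among the genes lower on the unsorted array, Slfn4 had a signal of 1539 against 12667 to 28038 on the sorted arrays, and Prtn3 (-3.69), Ric8a (-3.69), Itsn1 (-3.66), Ctsg (-3.15), the acute-phase genes Saa3 (-3.13) and Hp (-3.04), Acod1 (-3.07), Gpr84 (-3.01) and Isg20 (-2.89) were named with it. Itsn1 lay at the floor on the unsorted array, and it, Ric8a, Ctsg, Acod1, Gpr84 and Isg20 lay below its highest background control. Prtn3, Ctsg and Hp were lower still on Sca1+ replicate 2, with signals of 180, 22.2 and 432 against 223, 69.8 and 687 on the unsorted array. Chemokine and inflammatory genes had a median of -0.04, with 0 of 16 at least 2-fold below all 5 sorted arrays, and the macrophage median was -0.64, 0.05 after quantile normalization and -1.36 after median scaling. Interferon-stimulated and class I antigen presentation genes had a median of -1.11, with 7 of 33 at least 2-fold below all 5 sorted arrays. The unsorted array had an Actb 3' to 5' ratio of 1.01 and a spike signal of 1330. On the sorted arrays these were at least 1.87 and 5798, so the comparison coincides with a difference in these controls. Over 9965 genes, 705 were at least 2-fold above and 199 at least 2-fold below all 5 sorted arrays, against 194 and 363 after quantile normalization and 114 and 762 after median scaling. The median of all genes was 0.34, -0.03 and -0.44 under the 3 scalings; the interferon median stayed below it in each, at -1.15 after quantile normalization and -1.84 after median scaling.

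The feeder array was likewise described against the sorted fractions without a test. The highest genes were Myl9 (3.97), Cnn1 (3.67), Cxcl1 (3.62), Actg2 (3.61), Gas1 (3.56), Ccn2 (3.53), Lox (3.51), Col1a1 (3.47), Csrp1 (3.47) and Sparc (3.46), all but Actg2 at the floor on at least 1 sorted array. On Sca1+ replicate 2, Col1a1 (signal 20565 against 16207) and Sparc (18520 against 14631) exceeded the feeder array. The lowest were Hp (-6.20), Mpo (-5.49), Chil3 (-5.39 or lower, at the floor on the feeder array), Stfa3 (-5.29), Prtn3 (-5.27), Camp (-5.03), S100a8 (-4.73), Ltf (-4.66), Wfdc21 (-4.53) and Fpr2 (-4.42). Stellate cell, pericyte and smooth muscle genes had a median of 2.07, with 7 of 19 at least 2-fold above all 5 sorted arrays. Granulocyte genes had a median of -4.00, with 3 of 13 at least 2-fold below all 5 sorted arrays. Their median was -2.47 against the Sca1+ mean and -5.63 against the Sca1- mean. Over the 19 granulocyte genes measured, the median log2 signal was 6.35 on Sca1+ replicate 2 and 6.01 on the feeder array. Interferon-stimulated genes had a median of -1.07, with 11 of 33 at least 2-fold below all 5 sorted arrays. This comparison too coincides with a difference in controls. The Actb 3' to 5' ratio was 1.03 and the spike signal 1565 on the feeder array, against at least 1.87 and 5798 on the sorted arrays. Over 9027 genes, 229 were at least 2-fold above and 148 at least 2-fold below all 5 sorted arrays, and median scaling changed these counts to 120 and 299.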

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

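The control probe sets, which enter no comparison, stood highest on Sca1- replicate 1: the 3' to 5' ratio was 13.5 for Actb and 13.2 for Gapdh, against 1.01 and 0.865 on the unsorted array, and the geometric mean signal of 9 spiked hybridization control probe sets was 18256 against 1330. Of the tests in this part, the test of dilution on genes low in the feeder and that of feeder-layer cells were fixed before their result was seen, and those of 3' bias, of dilution for G2 and M phase genes and on genes abundant in the feeder, and of cell make-up, leukocytes and probe sets were chosen after it.

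Granulocyte and G2 and M phase genes were lower in Sca1+ as lists tested with camera at the preset correlation. Neither list passed with an estimated correlation in camera (adjusted p = 0.643 and 0.394) or with fry (adjusted p = 0.569 and 0.222). The tables argue against differing 3' bias as the whole cause, since within the second set, whose Actb ratios lie between 1.87 and 2.37, the granulocyte median was -4.51 with 10 of 13 members below 0 and the G2 and M phase median was -1.30. Dilution of Sca1+ replicate 2 by feeder-like RNA was examined as well, since a mixture lies between its sources. All 28 tested G2 and M phase members lay below both the feeder array and the second-set Sca1- mean, by a median of -0.73 (quartiles -1.01 and -0.59). After quantile normalization and median scaling 27 and 26 of 28 did, with medians of -0.66 and -0.60. Dilution by RNA as measured on this feeder array would not by itself give these values. The feeder array has no replicate and is of another platform and deposit set, so dilution is not settled for these genes. For the granulocyte genes, dilution as the whole cause of their fall on Sca1+ replicate 2 needs a share of feeder-like RNA of at least 95.6%. The 63 genes abundant in the feeder and at least 4-fold above second-set Sca1- reached a median of 45.1% of the feeder's level (quartiles 35.6% and 63.9%). These genes were picked by high signal on the same single feeder array that their level was divided by, which can lower the percentage. In the test fixed beforehand, 23.9% of 113 genes low in the feeder lay within 2-fold of second-set Sca1- or above it, which fell between its bounds. Such dilution therefore stays open for the granulocyte genes. A different cell make-up of the fractions, fewer granulocyte precursors and cycling cells in Sca1+, also stays open as a hypothesis: the highest of the 4 medians of both lists in both sets was -0.81, but the other haematopoietic lists went both ways, with medians of 0.37 for macrophage, 0.04 for erythroid, -0.21 for megakaryocyte and -0.31 for stem and progenitor genes.

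Mesenchymal genes were near the floor on the first-set sorted arrays and abundant on the second-set ones. The fibroblast list's median difference, first minus second set, was -3.35 over 25 genes. Of random lists matched on level, 95% lay between -0.54 and 0.35, so these genes fell further than most of that level. The test cannot decide on 3' bias, because the list was chosen for its low values and was not matched on transcript length. Feeder-layer cells in the second-set samples may account for the pattern. Their test took 50 genes abundant in the feeder (Col1a1 16207 and Sparc 14631 among them) and at most 100 on both first-set sorted arrays. Of these 50 genes, 39 (78.0%) exceeded 200 on all 3 second-set sorted arrays. This was just short of the share set beforehand, so feeder-layer cells stay open as an explanation. The median level of these genes was 56.6% of the feeder's on Sca1+ replicate 2 and 22.9% and 23.8% on Sca1- replicates 2 and 3. On the unsorted array, which is of the first set, it was 54.5%, and 47 of the 50 exceeded 200. Col1a1 (20565) and Sparc (18520) exceeded the feeder array's level on Sca1+ replicate 2. The feeder array has no replicate and is of the first set and another platform, so this excess does not settle the question. Mesenchymal transcripts of the progenitors themselves were not told apart from those of feeder cells. Whether the sort would remove feeder cells is not given in the sources used here.

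More macrophage than pan-endothelial genes exceeded the signal minimum on all 5 sorted arrays at once, though on Sca1+ replicate 2 it was 22 of 24 and 22 of 29, and on the unsorted array 21 of 24 and 23 of 29. Leukocytes in the sorted samples and leukocyte genes expressed by the progenitors cannot be told apart, because no array of progenitors freed of leukocytes was analysed: 79.2% of the macrophage list exceeded 100 on all 5 sorted arrays, which restates the observation, with signals from 24437 to 79825 for Lyz2 and from 18499 to 35387 for Csf1r, and 21 of 24 members also exceeded 100 on the feeder array. For the pan-endothelial list the share was 24.1%, and insensitive endothelial probe sets cannot be told apart from low expression, because no array of independent endothelial RNA was analysed here.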

How the results depend on the processing

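Without a block, 0 genes passed under every other setting run, except 1 with no filter, 85 with the deposit set as a block and 80, all lower, with the replicate number as a replicate block, which shares numbers 1 and 2 between the fractions; numbers 1 and 2 coincide with the deposit sets, and number 3 has 1 array. Leaving out an array gave 0 genes each time. Alternatives of the fit with the deposit set as a block, run after seeing the data, gave 0 genes with the higher floor, 0 with no filter, 40 with no intensity trend and from 53 (without Sca1+ replicate 1) to 2101 (without Sca1+ replicate 2) when an array was left out; without Sca1- replicate 1 the count was 232 and without Sca1- replicate 2 it was 210. Without Sca1+ replicate 1, Sca1+ replicate 2 or Sca1- replicate 1, the residual spread of the blocked fit came only from the difference between Sca1- replicates 2 and 3. Those arrays had r = 0.97 and may be technical repeats, so these counts do not show how many genes differ. Where an array left out leaves 1 array in a fraction, that array is assumed to vary like the others. The 3 lists became 5 with the higher floor, 6 with all probe sets, 5 with the mean of a gene's probe sets, 7 with the deposit set as a block, 5 with only the compared groups, 0 with an estimated correlation and 0 with fry, and from 2 to 15 (without Sca1+ replicate 1) when an array was left out, with 13 without Sca1+ replicate 2. Over 8 list medians, 130 values kept direction and call, 17 came to pass and 10 ceased to. The granulocyte and G2 and M phase lists passed each time an array was left out, with medians from -5.02 to -1.12 for granulocyte genes (-3.07 with all arrays) and from -1.16 to -0.92 for G2 and M phase genes. The S phase call was lost with the replicate number as a replicate block, without Sca1+ replicate 2 and without Sca1- replicate 2 or 3. The macrophage list came to pass with quantile normalization, signal above 300, all probe sets, the mean of a gene's probe sets, the replicate number as a replicate block and without Sca1+ replicate 2, the interferon list with all probe sets, without Sca1+ replicate 2 and without Sca1- replicate 1, and the megakaryocyte list with the higher floor, the mean of a gene's probe sets and only the compared groups. List medians that turned were pan-endothelial (from -0.25 without Sca1+ replicate 2 to 0.86) and fibroblast (from -2.02 without Sca1+ replicate 2 to 2.57; -0.47 without Sca1- replicate 1). Among named genes and list members, leaving out an array took Fli1 from -2.20 to 0.0017, Ifi47 from -0.088 to 1.98, Pdgfra from -0.98 to 2.64 and Postn from -1.19 to 2.82, the extremes coming without Sca1+ replicate 1 or 2, and with only the compared groups Fli1 turned to 0.18 and Sfrp1 to -0.25; 970 of the other values kept direction and side of the threshold and 24 came to pass it. The feeder counts against the unsorted array, 398 higher and 1548 lower, became 667 and 759 with quantile normalization, 880 and 688 with median scaling, 264 and 608 with the higher floor, 235 and 441 with signal above 300, and 751 higher with all probe sets. The unsorted counts against the sorted arrays, 705 above and 199 below, became 194 and 363 with quantile normalization, 114 and 762 with median scaling, 360 above with the higher floor, 271 above with signal above 300, 1450 above with all probe sets and 88 below with the mean of a gene's probe sets. The feeder counts against the sorted arrays, 229 above and 148 below, became 120 and 299 with median scaling, 773 above with all probe sets and 91 below with the mean of a gene's probe sets. Of the genes named without a test, 340 values moved by under 1 on the log2 scale, 20 by more and 0 turned. All probe sets and signal minima change the number of features counted; otherwise the cause was not tested. Planned tests of the feeder array were not run. Background controls of up to 170 limit what can be read of genes with low signal.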

Other observations

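Single members of the hepatoblast and biliary lists, picked out here after their values were seen, had higher signals on the unsorted array than on the sorted arrays. Epcam, an epithelial adhesion molecule, had a signal of 431 on the unsorted array and 391 on the feeder array, against at most 103 on a sorted array. Cldn4, which encodes a tight junction protein, had 304 and 293, against at most 76.8. Apoa1, which encodes the main protein of high-density lipoprotein, had 272 on the unsorted array and at most 28.6 on a sorted array, and lay under the floor on the feeder array. Other members did not follow: Afp had 502 and Alb 317 on Sca1+ replicate 2 against 297 and 288 on the unsorted array. Krt18 had 762 on the unsorted array but was not low on the second-set sorted arrays, with signals from 341 to 491.

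The interferon-induced antiviral genes Rsad2 and Ifit3, picked out after their values were seen, had lower signals on the unsorted and feeder arrays than on the sorted arrays, while 7 and 11 of the 33 members of the interferon list were at least 2-fold below all 5 sorted arrays. Rsad2 had 1659 and 1452 against 8804 to 16535 on the sorted arrays, and Ifit3 had 846 and 720 against 2754 to 6300. The unsorted and feeder arrays also had Actb 3' to 5' ratios of 1.01 and 1.03, against at least 1.87 on the sorted arrays. On the feeder array, DNA replication and S phase genes had a median of 0.49 above the unsorted array, at percentile 100 of the matched random lists, with 5 of 21 at least 2-fold higher, while macrophage genes had a median of -0.02, at percentile 2.48, with 0 of 21 differing 2-fold. After median scaling these medians were 0.85 and 0.34, against 0.28 for all genes.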
